A study of Mus musculus with 9 samples.

How the data were processed

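Gene expression in paw joints of male DBA/1 mice was measured on spotted cDNA arrays of cytokines, chemokines and other immune factors. Per the labels' protocols, total RNA was reverse-transcribed with array-specific primers and a 33P-labelled nucleotide, so each array carried 1 sample and 1 label. 9 arrays were analysed here, grouped by their titles: 3 early controls from naive mice aged 14 weeks, 2 peak controls aged 18 weeks (replicates 2 and 3), 3 decline controls aged 22 weeks and 1 array from a mouse with early collagen-induced arthritis (CIA, replicate 3) aged 14 weeks. The series design text gives 3 mice per group. The other arrays of that design were not analysed here. Per the labels, the submitters left the decline controls out of their own analysis because control spots and housekeeping genes were weak, and label incorporation was hard to detect for decline control replicate 3.

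Per the file headers, each deposited array file gives, for 1536 spots, an unnormalized spot density, a local background and a background-subtracted density, all of them intensities. The deposited subtracted density differed by at most 0.00800 from density minus background with negative values set to 0. The image software is not given in the sources used here. The series' deposited value table lists 532 features by grid position, from A1U to P24U. Comparison with the array files showed that each deposited value of this table is a ratio: the mean over 2 neighbouring spots of density divided by local background. Each array of that table carries 1 scale factor, whose rule is not given in the sources used here; the column medians ran from 99.3 to 99.9. The letter and number of a feature give the pair of rows and the pair of columns on the grid, and U or L the upper or lower row. For 6 arrays the value table was proportional to the array file of the same sample. Each of the 3 decline control columns was instead proportional to the array file of another decline control. The group is the same, so only the replicate numbers within it are uncertain, and the numbers of the array files are used below.

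The files do not pair positions with genes, and no table used here does. Features are therefore reported by position, at most 2 in each direction per comparison, and it is not known which are housekeeping genes or control spots. All 532 features entered the tests, so some of them may be controls. The gene list tests and the scaling to housekeeping genes planned before the data were examined could not be run. For the same reason, detection was set against local background and not against negative controls.

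Values were computed from density and local background with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, values were taken to log2, the 2 spots of a feature were averaged, and the arrays of a fit were quantile normalized. Quantile normalization gives all arrays 1 distribution, so a shift of most features in 1 direction would not be seen. Linear models with 1 mean per group were fitted with lmFit and eBayes, with Benjamini-Hochberg adjustment over 532 features and a threshold of 0.05, two-sided. 1 fit held the early controls, peak controls and the CIA array, and another the 8 control arrays. In the first, the spread came from the 5 control arrays alone, with 3 residual degrees of freedom, and the single CIA array is assumed to vary like them. A feature counted as above background on an array when both of its spots had a density above their local background. Array signal and detection were compared with exact permutation tests. The number of arrays limits the precision, and the p-values rest on the spread between mice and arrays together.

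The rule for named features was fixed before the data were examined: they were those with the largest differences past the threshold. Where none passed, they were those with the largest differences whose CIA value lay outside the range of all 5 early and peak controls and which were above background on the higher side. The planned numbers per comparison were larger, but without gene names the first 2 in each direction are given. A feature that was not above background on any array of a group has only a bound there. Its fold is then computed against, for each array, the higher of its own value and the lowest value among features above background.

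The fits were tested on simulated data, with 30 features changed 2-fold and 30 changed 4-fold among 532 in each of 20 simulations. For the CIA comparison, 53.3% of the 2-fold and 87.2% of the 4-fold changes were recovered, and 4.64% of the calls were false. For peak against early controls, recovery was 76.2% and 94.0%, with 7.35% false calls. For decline against early controls it was 49.7% and 89.7%, with 4.57% false calls. These rates describe the simulated values, and whether they hold for the measured arrays was not tested. The measured arrays were unequal in noise: the log2 SD between spots of a feature was 0.207 on peak control replicate 2. On the other early, peak and CIA arrays it was 0.0641 to 0.0753. Decline controls lay close to background, with median ratios of density to background of 1.06 to 1.08. In the CIA comparison, a simulated 4-fold change, 2 on the log2 scale, had a mean estimate of 1.72 with quantile normalization and of 1.99 on the same simulated values without it. Alternatives covered the scaling, the background correction, a filter on dim features, the value table, the threshold, a replicate block, the arrays in the fit and each array left out.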

Results

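The array set comprised 9 arrays from paw joints of DBA/1 mice, a strain in which immunization with type II collagen induces arthritis. There were 3 early, 2 peak and 3 decline controls from naive mice aged 14, 18 and 22 weeks, and 1 array from a mouse in the early phase of CIA at 14 weeks. Each array reported 532 features, which the files name by grid position and not by gene. The design addresses how immune factors in the joint differ between arthritic and naive mice of the same age. The controls of different ages also allow naive joints to be compared over time.

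Signal over background separated the decline controls from all other arrays. The median ratio of spot density to local background was 2.32 ± 0.154 (SD, n = 3) in early controls and 2.22 ± 0.778 (SD, n = 2) in peak controls. It was 2.61 on the CIA array and 1.07 ± 0.00961 (SD, n = 3) in decline controls. Both spots of a feature exceeded their background for 502.7 ± 6.11 features (SD, n = 3) in early controls and 478 ± 53.7 (SD, n = 2) in peak controls. They did so for 507 features on the CIA array, but for 337.3 ± 14.6 (SD, n = 3) in decline controls. Against the 5 early and peak controls, the decline controls differed by -155.5 features above background (exact permutation test, two-sided, p = 0.0179). By the same rule, 17.2% to 19.4% of the grid positions that the value table does not list, the corners left out, were above background on decline controls. On the early, peak and CIA arrays it was 13.4% to 23.3%, so this rate is not particular to the decline controls. Against the mean plus 2 SD of those positions, 241, 50 and 189 features passed on decline control replicates 1, 2 and 3, where 353, 335 and 324 had both spots above local background. On peak control replicate 2, 307 passed, where 440 had both spots above local background. On the other early, peak and CIA arrays, 453 to 474 passed. Median spot density was 5277 to 5662 in decline controls against 77283 to 149148 in early and peak controls, and median local background 4784 to 5087 against 26747 to 63832. The difference in median log2 intensity was -6.14 after background correction (exact permutation test, two-sided, p = 0.0179), a size that depends on the correction where density is this close to background. It was -4.15 without background correction and -1.07 as the log2 ratio of density to background (exact permutation tests, two-sided, p = 0.0179 for each). That p is the smallest that 56 splits allow.

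**Figure D1:**
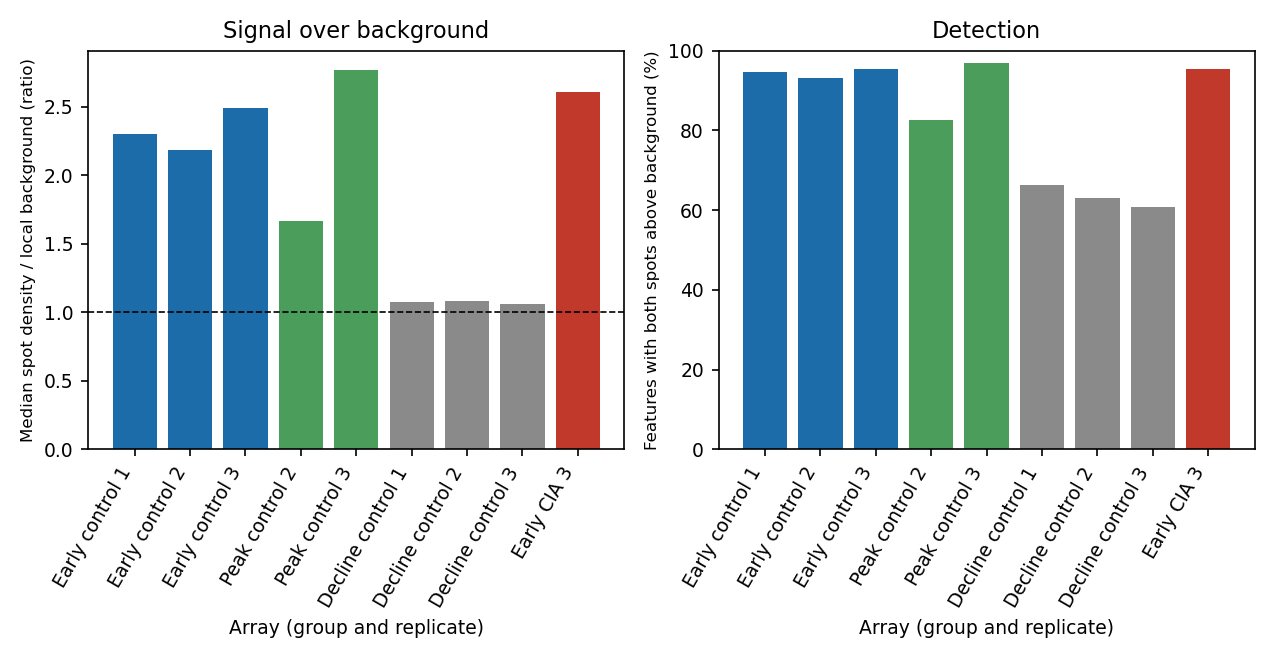
Bars show, for each of the 9 arrays, the median ratio of spot density to local background over 532 features (left, dashed line at a ratio of 1) and the percentage of features with both spots above background (right). The 3 decline controls lie close to a ratio of 1, at 1.06 to 1.08, and have 60.9% to 66.4% of features above local background. Of the unlisted positions, 17.2% to 19.4% also meet that rule on these arrays, and 13.4% to 23.3% on the other arrays.

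Replicate arrays of the early controls agreed closely. Across features, normalized log2 intensities of early control pairs had Pearson's r of 0.991 to 0.993, and the CIA array had r of 0.980 to 0.985 with them. The 2 peak controls had r = 0.937 with each other. Peak control replicate 2 stood apart from the other arrays of this fit, with r of 0.910 to 0.937 against 0.952 to 0.993 among the rest. On it, the SD between the 2 spots of a feature was 0.207 on the log2 scale, against 0.0641 to 0.0753 on the other early, peak and CIA arrays, and 440 features were above background. Decline control pairs had r of 0.761 to 0.865 in a normalization over all 9 arrays. These correlations are across features, which are not independent replicates.

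Early CIA was compared with early controls of the same age to ask which features differ in the arthritic joint. No feature passed the threshold in limma, with a lowest adjusted p of 0.156. At an unadjusted p under 0.05, where chance gives 26.6 of 532, there were 38 features, 24 higher and 14 lower. That count was 86 without peak control replicate 2, 84 without peak control replicate 3, 25 without early control replicate 2, 21 without early control replicate 3, 17 with median scaling, 9 with the value table of the series and 2 without background correction. The sizes were small: 16 features differed by 1.5-fold or more, 9 of them higher and 7 lower, and 2 differed by 2-fold or more. The CIA array lay outside the range of the 5 early and peak controls for 186 features (35.0%), where chance gives 33.3% if all arrays vary alike. The peak controls, of another age and less alike than the early controls, widen that range. The share therefore cannot show whether the CIA array differs from the early controls. For 457 of 532 features (85.9%) the 95% confidence interval of the difference lay within a 2-fold change in either direction. These intervals hold no spread between CIA mice, as the single CIA array is assumed to vary like the controls.

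The highest difference was that of feature L5L, at 17.3 on the CIA array against 14.6 ± 0.611 (SD, n = 3) in early controls on the log2 scale. This is a difference of 2.72 with a 95% interval of 0.54 to 4.90, and limma's adjusted p was 0.513; without background correction the difference was 0.15. L5L was above background on 1 of the 3 early controls, and peak control replicate 3, from a naive mouse, read 17.0. M24U was above background on the CIA array and on none of the 3 early controls, so only a bound can be given: with normexp correction it was at least 2.01-fold higher on the CIA array (adjusted p = 0.156 in limma). The bound did not hold under other treatments of the background, where the log2 difference was 0.71 with the value table of the series, 0.83 with median background and 0.97 without correction. The lowest were K4U, with a difference of -0.80 ± 0.13 (SE; adjusted p = 0.237 in limma), and B2U, with -0.79 ± 0.32 (SE; adjusted p = 0.704 in limma). Both were above background on all arrays compared. With the value table of the series, the differences of L5L and B2U were 1.59 and -0.48, and against early and peak controls as 1 group that of K4U was -1.21. With 1 CIA array, the disease group has no replicate check of its own. Differences of adjacent grid positions correlated at 0.125 in this comparison, so uneven signal across the membrane stays open for these features.

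**Figure D2:**
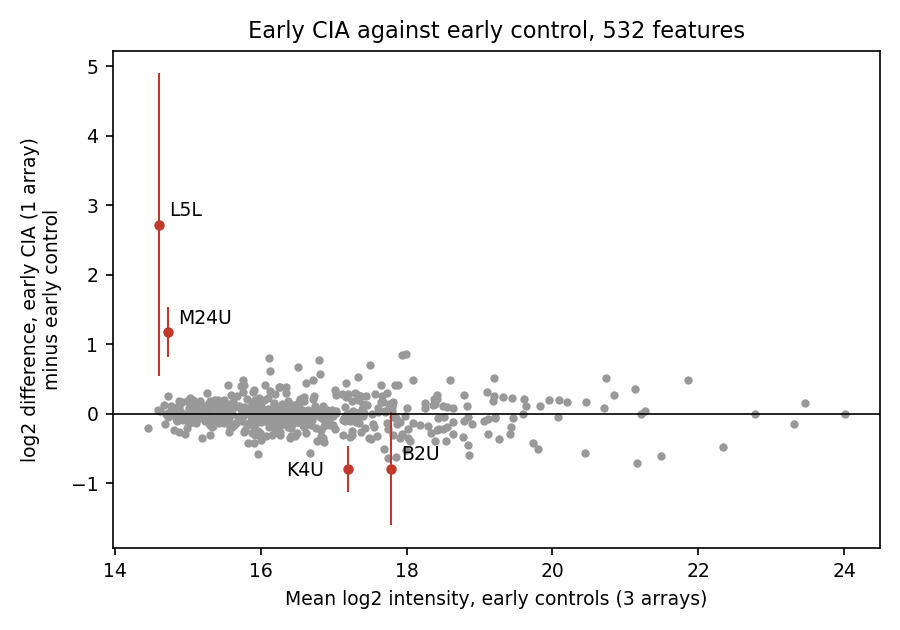
Each point is 1 of 532 features, with its mean log2 intensity in 3 early controls (x axis) and the log2 difference between the CIA array and that mean (y axis). The 4 named features are red, with 95% confidence intervals from limma; L5L and M24U lie at the low end of the intensity range, at 14.6 and 14.7, and M24U was above background on none of the early controls.

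Peak and early controls were compared as naive joints at 18 and 14 weeks. 14 of 532 features passed the threshold in limma, 5 higher and 9 lower in peak controls, with sizes from 0.69 to 1.88 on the log2 scale. The balance of directions moved with the setting: it was 1 higher and 3 lower with median scaling, 40 and 31 at an adjusted p threshold of 0.1, 17 and 16 without peak control replicate 2, and 93 and 81 without peak control replicate 3. J16L rose by 1.37 ± 0.18 (SE), from 16.8 ± 0.138 (SD, n = 3) to 18.2 ± 0.348 (SD, n = 2; adjusted p = 0.0252 in limma). O13L rose by 1.25 ± 0.11 (SE), from 17.9 ± 0.114 (SD, n = 3) to 19.2 ± 0.0632 (SD, n = 2; adjusted p = 0.0172 in limma). L19U fell by 1.88 on the log2 scale with an SE of 0.25, from 18.9 ± 0.0389 (SD, n = 3) to 17.0 ± 0.594 (SD, n = 2; adjusted p = 0.0252 in limma). H22L fell by 1.53 with an SE of 0.18, from 17.8 ± 0.278 (SD, n = 3) to 16.3 ± 0.0449 (SD, n = 2; adjusted p = 0.0225 in limma).

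For all 14 called features, both peak controls lay on the same side outside the range of the 3 early controls. The call itself favours this order, so it is no separate support. Over all features, the order held for 247 of 532 (46.4%), where chance gives 20% if all early and peak arrays vary alike. They did not: pairs of early controls had r of 0.991 to 0.993, and the 2 peak controls had 0.937. Peak arrays that vary more would raise this share without a change in common, so it is no evidence of one. The count depended on single arrays: it was 1 without early control replicate 1, and 0 without replicate 2 or without replicate 3. Fits without 1 peak control hold 1 peak array, and their spread comes from the early controls alone. Their counts are therefore no check of the peak difference. J16L, O13L, L19U and H22L had differences of 1.15, 1.23, -1.49 and -1.56 without peak control replicate 2. They had 1.62, 1.32, -2.27 and -1.53 without peak control replicate 3. No feature passed in limma without background correction or with the value table of the series, where 39 and 83 features had an unadjusted p under 0.05. O13L then had a difference of 0.66 without background correction, and H22L one of -0.86 with the value table.

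**Figure D3:**
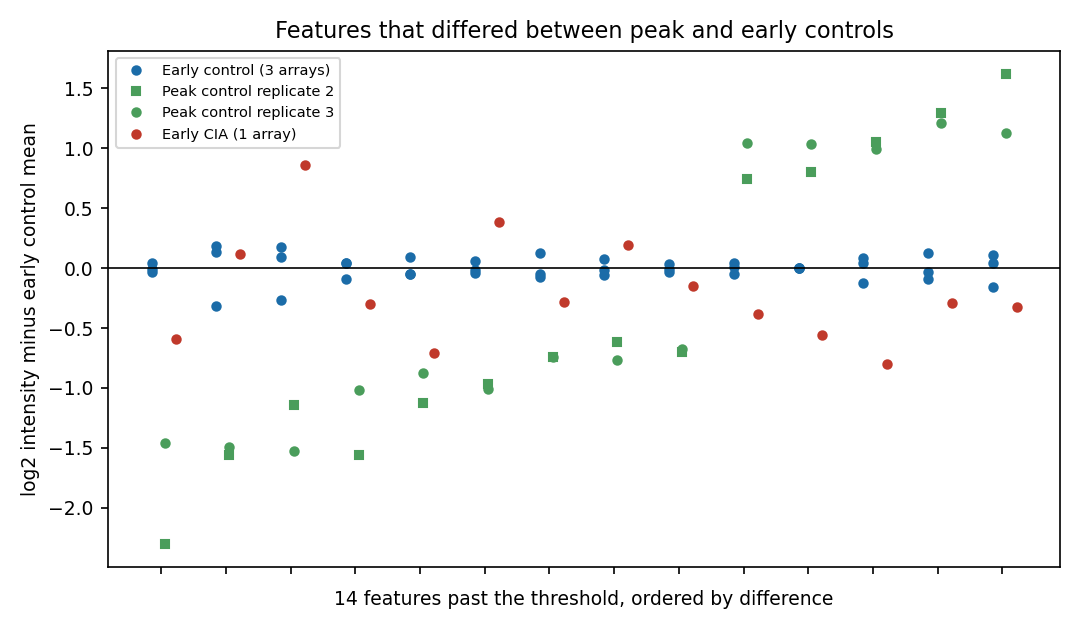
For the 14 features past the threshold between peak and early controls, ordered along the x axis by their difference, points show each array's log2 intensity minus the early control mean (y axis). Both peak controls lie to the same side of all 3 early controls for each of the 14 features, an order that the selection of these features favours. The CIA array is shown for comparison and was not part of that difference.

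Decline and early controls were compared as naive joints at 22 and 14 weeks, and the arrays that the labels call weak are those of the 22-week group. 31 features passed the threshold in limma, 16 higher and 15 lower in decline controls. P1U and P24U, both at corners of the grid, had the largest rises on the log2 scale with quantile normalization. With median scaling these rises were 0.69 and 0.53 and did not pass in limma. Before normalization, median log2 signal averaged 10.1 in decline controls and 16.2 in early controls. A rise is thus relative to the other features of an array and does not show a brighter spot. The unlisted positions below them, P1L and P24L, had lower log2 ratios to background on decline controls. These were 1.09 to 1.66 and 1.10 to 1.44, against 1.86 to 3.69 and 2.90 to 3.83 on early controls. P1U rose by 1.66 ± 0.37 (SE), from 16.5 ± 0.579 (SD, n = 3) to 18.2 ± 0.463 (SD, n = 3; adjusted p = 0.0491 in limma). P24U rose by 1.62 ± 0.23 (SE), from 16.6 ± 0.0411 (SD, n = 3) to 18.2 ± 0.281 (SD, n = 3; adjusted p = 0.0296 in limma). F22U fell by 1.53 with an SE of 0.34, from 14.7 ± 0.205 (SD, n = 3) to 13.2 ± 0.663 (SD, n = 3; adjusted p = 0.0491 in limma), and was above background on 1 of 3 decline controls. E19U was above background on all 3 early controls and on no decline control, and was at least 1.51-fold lower there with normexp correction (adjusted p = 0.0491 in limma), a bound that did not hold with median background or without correction. Of the 15 lower features, 7 were above background on all 3 decline controls. Of the 16 higher features, 4 were above background on none of the early controls. The count was 0 without any 1 of the 3 early controls, 11 without peak control replicate 2, 10 without peak control replicate 3, 128 without decline control replicate 1 and 19 without decline control replicate 3. It was 9 among features above background on at least 2 arrays and 12 with only early and decline controls, and in both P1U, F22U and E19U no longer passed. It was 42 without decline control replicate 2 and 245 with median scaling. It was 0 in limma without background correction or with the value table of the series, where 120 and 107 features had an unadjusted p under 0.05. Without background correction the differences of F22U and E19U were -0.75 and -0.24, and with the value table those of P1U, P24U and E19U were 1.05, 0.57 and -0.81.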

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

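Median background in place of normexp, array signal as density with no correction or over background, detection against unlisted positions and the fit of early arrays alone were chosen after seeing the data; the other alternatives were planned. The count of 0 features between early CIA and early controls held under all 17 alternatives run with limma, with a lowest adjusted p from 0.0973 to 1 and with 2 to 87 features at an unadjusted p under 0.05. All 17 rest on the same CIA array, so none of them varies the disease group, and the threshold of 0.1 reuses the main fit. L5L, K4U and B2U kept their direction in all 17, and M24U in the 16 that included it. L5L ranged from 0.15 to 3.17 on the log2 scale. Peak against early controls gave 14 features, which became 4 with median scaling and 71 at an adjusted p threshold of 0.1. They became 0 without background correction, 0 with the value table of the series and 0 with the replicate number as a replicate block, where 39, 83 and 68 features had an unadjusted p under 0.05. Leaving out 1 array at a time gave 0 to 174. Median scaling moved the median difference of all features to 0.10 on the log2 scale. Decline against early controls gave 31 features, which became 245 with median scaling, 56 at a threshold of 0.1, 9 among features above background on at least 2 arrays and 12 with only early and decline controls. They became 0 without background correction, 0 with the value table and 0 with the replicate block, where 120, 107 and 119 features had an unadjusted p under 0.05. Leaving out 1 array gave 0 to 128. The cause of these moves was not tested. No named feature reversed, but the 4 from peak controls lost the threshold in 6 or 7 of 15 alternatives and the 4 from decline controls in 7 to 13 of 18. Deviations of same-numbered early and decline controls correlated at -0.068 to 0.034. The decline replicate numbers are uncertain and those arrays weak, so this cannot decide whether the numbers pair the arrays. Array signal and detection of the decline controls kept their direction and an exact permutation p under 0.05 in 12 of 12 and 10 of 10 alternatives. In each case 8 of these left out 1 array. All decline controls lay below all early and peak controls on both measures, so those 8 runs had to keep that order and are no independent check. Differences ranged from -6.58 to -1.07 for log2 signal and from -279.7 to -148.8 for features. The median r of replicate pairs was 0.937, and 0.782 without background correction. Scaling to housekeeping genes, gene list alternatives and detection against marked negative controls were not run, since the files mark no such spots or genes. Signal over background limits the decline arrays.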

Other observations

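The tests of the correlation between the 2 peak controls, of that between peak and decline controls and of calls towards the middle of the range were chosen after the result was seen, as was the margin of 2 SD required of the adjacent-position test. The other tests that weigh an explanation of the peak and decline differences below were planned before it.

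The array files hold 236 grid positions that the value table does not list. 4 of them, the lower partners of the corner features, were bright, with a median log2 ratio of density to background of 3.53 over the 3 early controls. On peak control replicate 2 they read 0.36 to 3.50, on peak control replicate 3 3.54 to 3.91, on early controls 1.86 to 4.09 and on decline controls 1.05 to 1.73. The other 232 had a median of -0.021, and none had a mean above 0.097 in early controls. On the CIA array the 4 corner positions read 3.55 to 4.03, below the highest of the 8 control arrays or above it by less than the SD of the 5 early and peak controls. No other unlisted position passed that limit on the CIA array while also lying over 3 SD above the mean of the unlisted positions there. The files do not say what these positions hold.

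The replicate numbers of the decline controls differ between the 2 kinds of file. The array file of replicate 1 was proportional to the value table's column of replicate 3, that of replicate 2 to the column of replicate 1, and that of replicate 3 to the column of replicate 2. Against the column of its own number, r on the log2 scale was 0.779, 0.907 and 0.824.

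Peak control replicate 2 was the noisiest of the early, peak and CIA arrays, so the differences between peak and early controls may come from that array alone. Against this, the differences of the 2 peak arrays correlated across 532 features with r of at least 0.369 in all 6 arrangements. In each arrangement the 2 differences were taken from different early controls. The count of features passing without peak control replicate 2 is no check here, as the spread then comes from the early controls alone. Differences of adjacent positions correlated at 0.0397 (permutation p = 0.253, one-sided), below the 0.1 set beforehand as the limit against uneven signal across the membrane, but by only about the SD of permuted positions, 0.0603; the unlisted corner positions, which that test and its limit left out, read 0.36 to 3.50 on peak control replicate 2, so uneven signal stays open. A change with age that goes on to 22 weeks stays open too, as peak and decline differences taken from different early controls correlated at 0.160 to 0.255 on weak decline arrays. A shared hybridisation day of the peak arrays was not tested, as the labels give no batch.

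Differences between decline and early controls may come from signal close to background, which narrows the range of intensities. The slope of each decline control's log2 intensity on the early control mean was at most 0.602 after median scaling, but the calls were made after quantile normalization, which gives all arrays 1 range, so this slope does not decide it. The same slope was 0.688 for peak control replicate 2 and 0.934 to 1.01 for the other early and peak controls. Of the 31 calls, 24 moved towards the median level of the peak controls and 7 away from it, against 332 of all 532 features (62.4%) towards it, which leaves this explanation open. Age, untested, and uneven signal across the membrane stay open too. The arrays that the labels call weak and the age fall in 1 group. Differences of adjacent positions correlated at 0.0841, where permuted positions had an SD of 0.0602 (permutation p = 0.0849, one-sided). The real split of the 6 arrays gave 31 features and was the only 1 of 10 splits to give as many, with a highest other count of 0; 10 splits are too few for a share under 0.05.

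Between the CIA array and early controls, differences of adjacent positions correlated at 0.125 (permutation p = 0.0120, one-sided; 0.0360 after Benjamini-Hochberg adjustment over 3 comparisons). That is above the 0.1 used as a limit for the other comparisons. Uneven signal across the membrane therefore stays open for the CIA differences, those of L5L, M24U, K4U and B2U included.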
